A study of Mus musculus with 6 samples.

How the data were processed

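Gene expression was measured on single-colour Affymetrix arrays with biotin-labelled cRNA, made from total RNA of the mouse gastric corpus. There were 6 arrays, 3 from untreated controls and 3 from mice given dexamethasone, and the labels call the samples of each group biological replicates. The deposited table holds 1 log2 expression value per probe set and array, made by the authors with RMA (robust multi-array average), per the submitters' processing notes, which name R 2.9, limma and RMA without saying what each was used for. The version of the chip definition and any filter are not given in the sources used here. As RMA normally includes quantile normalization, array-wide shifts between the groups would have been removed before deposit, so each change below is relative to the bulk of the genes on the array. RMA also compresses differences of dim probe sets.

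The table has 20985 probe sets. Their names end the way a custom chip definition with 1 probe set per gene does. In the platform annotation used here, 19921 probe sets had 1 gene symbol, 0 had several and 1064 were not listed, which leaves these unnamed and outside the gene tests. For the 2 symbols carried by 2 probe sets (Ahnak2 and Rnf213), the probe set with the higher mean over the 6 arrays was taken, which gave 19919 genes. Of these, 19808 gene IDs were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. No coordinates are printed, since no build is named for the array. The number of arrays, 3 per group, limits the precision of every value.

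Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, no filter on level, two-sided), with Benjamini-Hochberg adjustment over the 19919 genes and a threshold of 0.05 on the adjusted p. Every adjusted p for a gene comes from limma. Standard errors (SE) are limma's moderated ones, and folds are 2 to the power of the log2 change. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so none is given for single genes. Before the data were examined, 36 gene lists were fixed from textbook knowledge: pathways, gastric cell types and markers of other cell types that the dissected tissue could hold. The arginine list was set apart from the rest because of remembered published work on glucocorticoids and L-arginine in the stomach, which is no part of the sources used here. They name 572 genes, of which 37 were not measured. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists. Every adjusted p for a list comes from camera unless fry is named. Camera with the correlation estimated for each list and fry were run beside it. For each list the number of members past the threshold is given over all genes and adjusted over the list alone.

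The genes named were also set by a rule fixed at that point. It takes the 12 largest rises and 12 largest falls among the genes past the threshold whose groups do not overlap, leaving out predicted genes, olfactory genes and ribosomal pseudogenes. It adds 8 check genes of glucocorticoid action (Fkbp5, Tsc22d3, Per1, Zbtb16, Nr3c1, Nr3c2, Hsd11b1 and Hsd11b2), up to 4 members of smallest p in each list described, and each arginine gene past the threshold adjusted over the list alone. Any other gene named is said to have been chosen after its values were seen.

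The alternatives tried were the replicate number as a block, arrays centred on their median, quantile normalization, leaving out the dimmest 40% of genes, other choices among probe sets of 1 gene, a prior with trend and robust settings, array weights, all probe sets, a minimum absolute log2 change of 1, and each array left out in turn. One more was added after seeing the data: each array's mean over the squamous epithelium list as a covariate. The scripts were tested on simulated data with 19919 genes. For the comparison of dexamethasone with control, 84% of 50 genes changed by 0.5 on the log2 scale were recovered, 100% of 50 at 1, 98% of 50 at 1.5 and 100% of 50 at 2, with 14 unchanged genes called. A list shifted by 0.3 was called, as was 1 of 35 lists that were not shifted. The simulated genes were drawn independently, so this says nothing on false calls of lists whose genes move together. Their noise was normal, with limma's moderated variances and no structure shared across genes within an array. Recovery in the real data may therefore be lower.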

Results

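The expression of 19919 genes was measured in the gastric corpus, the acid-secreting body of the stomach, of female wildtype Balb/c mice aged 8 to 12 weeks. In 1 group of 3 samples the mice drank water with dexamethasone, a synthetic glucocorticoid, at 50 mg per litre over 3 days, renewed on day 2. The other group of 3 was left untreated. The comparison asks which genes of the corpus differ in level under the steroid. Pearson correlations across genes, which are not independent replicates, ranged from 0.987 to 0.993 over the 3 pairs of control arrays, from 0.988 to 0.996 over the 3 pairs of dexamethasone arrays and from 0.983 to 0.990 over the 9 pairs between groups. Array medians lay between 7.94 and 7.98 on the log2 scale. The first principal component held 43.3% of the variance. On it, dexamethasone replicates 1 and 2 lay at 17.8 and 19.3, while dexamethasone replicate 3 lay at -1.43 and the controls at -16.0, -4.08 and -15.7. The mean over the markers of squamous epithelium, the lining of the neighbouring forestomach, differed within both groups. It was 9.94 and 9.93 in dexamethasone replicates 1 and 2 and 9.59 in control replicate 2, against 8.25, 8.39 and 8.50 in control replicates 1 and 3 and dexamethasone replicate 3.

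Among the genes chosen as a check of the treatment, Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose 3.68-fold (log2 change 1.88, SE 0.26, n = 3 per group, limma adjusted p = 0.0151). Nr3c2, the mineralocorticoid receptor, fell (log2 change -0.58, SE 0.063, adjusted p = 0.00550). The glucocorticoid receptor gene Nr3c1 had a log2 change of -0.16 (SE 0.055, adjusted p = 0.247). Zbtb16 stood at 0.75 (adjusted p = 0.120), Tsc22d3 at 0.33 (adjusted p = 0.591) and Per1 at 0.22 (adjusted p = 0.770). Hsd11b1 and Hsd11b2, whose enzymes activate and inactivate glucocorticoids, had log2 changes of 0.24 and -0.24 (adjusted p = 0.215 and 0.216). Of the 30 glucocorticoid target genes in the list, 6 rose, 0 fell and 24 did not pass, and 11 passed adjusted over the list alone, each higher. Lcn2 (lipocalin 2) rose 4.78-fold, Sult1a1 (a sulfotransferase) 2.98-fold and Tgm2 (transglutaminase 2) 2.04-fold. Camera placed the list above the other genes (median log2 change 0.32, adjusted p = 1.61e-12; adjusted p = 0.220 with an estimated correlation), and the median was 0.495 without control replicate 1. Control replicate 1 lay at -0.03 for the mean of this list relative to the 6 arrays, against -0.38 and -0.37 in control replicates 2 and 3. Fkbp5 lost its call without control replicate 2 (adjusted p = 0.0503), control replicate 3 (0.0957) or dexamethasone replicate 2 (0.0883). The count of called targets was 3 without control replicate 2, control replicate 3 or dexamethasone replicate 2.

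Over all genes, 367 changed under dexamethasone, 159 higher and 208 lower (limma, 1.84% of those tested), and 2612 had an unadjusted p under 0.05. Of the 367, 48 changed by 1 or more on the log2 scale, 26 higher and 22 lower. In each of the 367 the groups did not overlap, which was also true of 18.3% of all genes, where chance gives 10%. The largest rise was Lyz1, the lysozyme of Paneth cells, at 10.5-fold (log2 change 3.39, SE 0.57, adjusted p = 0.0337). Its dexamethasone values were 11.6, 12.0 and 9.45, with controls between 7.55 and 7.72. Next came Serpina3n, a serine protease inhibitor, at 6.37-fold (log2 change 2.67, SE 0.13, adjusted p = 0.000190). Klk1 (tissue kallikrein) rose 5.30-fold, Lcn2 4.78-fold and Fmo2 (a flavin monooxygenase) 4.30-fold. C7, Dpep1, Sult1a1, Pdk4 and F13a1 rose by log2 changes of 1.70, 1.62, 1.58, 1.57 and 1.55. The largest falls were in the gasdermin genes Gsdmc3, 15.8-fold lower (log2 change -3.98, SE 0.39, adjusted p = 0.00404), and Gsdmc2, 8.67-fold lower (log2 change -3.12, SE 0.21). Nqo1, a quinone reductase, was 4.76-fold lower (log2 change -2.25, SE 0.073, adjusted p = 5.85e-05). Akr1b8, an aldo-keto reductase, and Gsta3, a glutathione transferase, fell 2.87-fold and 2.82-fold. Gbp4, a guanylate-binding protein induced by interferon, fell 2.65-fold. Close paralogs of Lyz1, Klk1, the Gsdmc genes and the histocompatibility genes can share probes, so the split of the signal among them is uncertain. The count of 367 was 178 without control replicate 2, 92 without control replicate 3, 118 without dexamethasone replicate 1 and 88 without dexamethasone replicate 2, and the 159 higher genes were 284 without dexamethasone replicate 3.

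Of the 24 largest changes named under the rule above, 18 stayed past the threshold without each array in turn. Fkbp5 is described above. Lyz1 lost its call without control replicates 1, 2 or 3 (adjusted p = 0.0602, 0.0876 and 0.173) or dexamethasone replicates 1 or 2 (0.146 and 0.122), as well as with a prior with trend and robust settings (0.145). Pdk4 lost its call without control replicates 2 or 3 (0.0635 and 0.0697) or dexamethasone replicates 1 or 2 (0.0792 and 0.0885). C7 lost its call without control replicate 3 (0.102) or dexamethasone replicates 1 or 2 (0.0870 and 0.0742). For Igha it was control replicate 2 (0.0697) and dexamethasone replicates 1 and 2 (0.124 and 0.130), besides the trend and robust prior (0.0509), and for Nr1d1 control replicate 3 (0.172) and dexamethasone replicates 1, 2 and 3 (0.146, 0.131 and 0.0538).

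**Figure D1:**
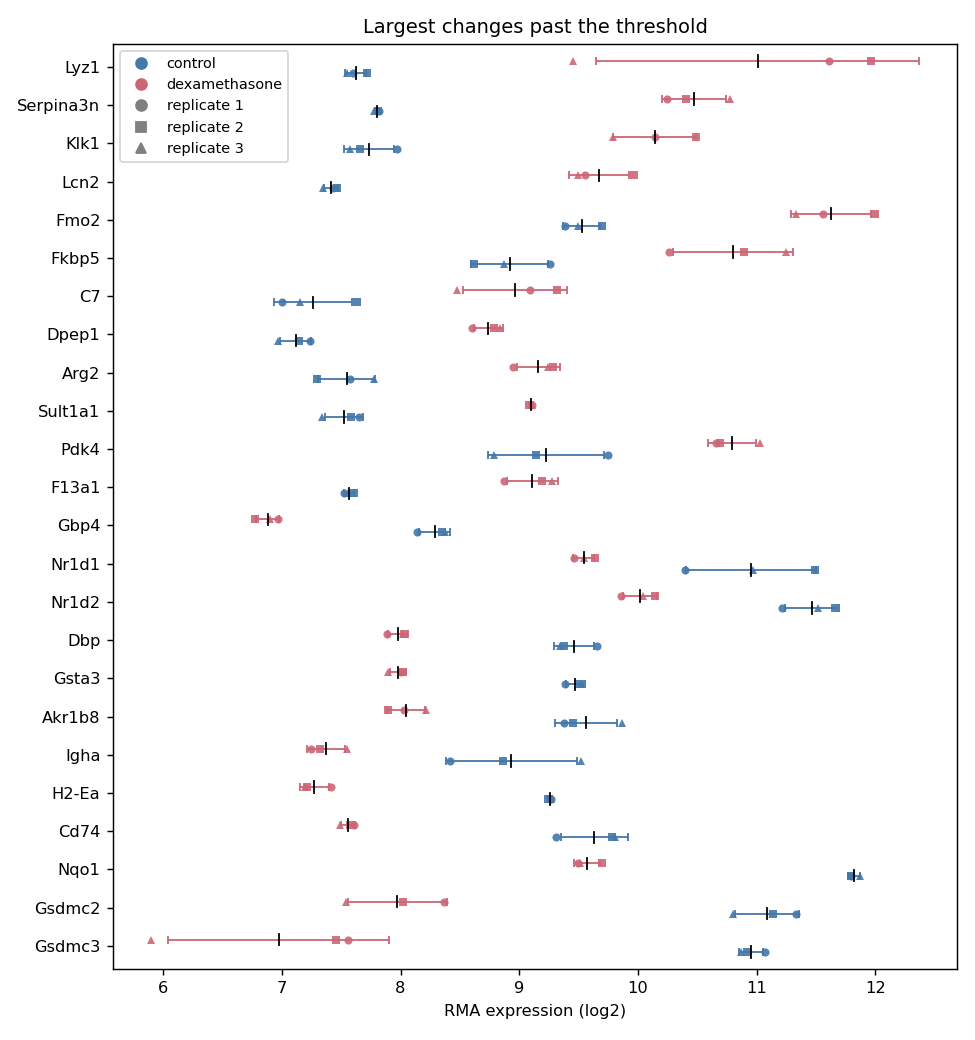
RMA expression (log2) of the 24 genes with the largest changes past the threshold under the naming rule, 12 higher and 12 lower. Probe sets without a gene symbol were not ranked. Points are single arrays shaped by replicate, the upright mark is the group mean and the bar is the SD (n = 3 per group). For Lyz1 the dexamethasone arrays lie at 11.6, 12.0 and 9.45 while controls lie between 7.55 and 7.72, and for Gsdmc3 the mean falls from 10.95 to 6.97.

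Of the 8 measured genes of major histocompatibility class II presentation, 4 fell, 0 rose and 4 did not pass, and the same 4 passed adjusted over the list alone. Cd74, the invariant chain, fell 4.21-fold (log2 change -2.07, SE 0.13, adjusted p = 0.000761), H2-Aa 2.58-fold, H2-Ab1 2.36-fold and H2-Eb1 1.68-fold (limma adjusted p = 0.0424). H2-Ea, outside the list, fell 3.95-fold. Camera placed the list below other genes (median log2 change -0.45, adjusted p = 1.26e-06, and adjusted p = 0.220 with an estimated correlation). The list's median was -1.3 when the dimmest 40% of genes were left out, a setting that kept the 4 called genes alone. H2-Eb1 lost its call without control replicates 2 or 3 (adjusted p = 0.116 and 0.199) or dexamethasone replicates 2 or 3 (0.167 and 0.0751), as well as with the replicate block (0.0994), quantile normalization (0.0505) or the squamous covariate (0.0527). Of 17 interferon-stimulated genes, 2 fell, Iigp1 1.78-fold and Oasl2 1.46-fold, 15 did not pass, and 7 were lower adjusted over the list alone (camera adjusted p = 2.35e-06; adjusted p = 0.220 with an estimated correlation). The count of 2 was 1 without control replicate 2, control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2. Igha, the heavy chain of immunoglobulin A, fell 2.95-fold (log2 change -1.56, SE 0.25, adjusted p = 0.0263).

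Markers of immune cells gave few calls. Among 26 cytokine and inflammation genes, the chemokine gene Cxcl13 rose 2.48-fold (log2 change 1.31, SE 0.205, adjusted p = 0.0252), Icam1 rose (log2 change 0.39) and Cxcl10 fell (log2 change -0.38), with 23 not past the threshold. Adjusted over the list alone, 3 were higher and 1 lower. Their median of -0.018, mean of 0.038 and upward camera direction differed in sign (camera adjusted p = 0.872). The 3 calls of this list ended without control replicate 2, control replicate 3 or dexamethasone replicate 2, and only Cxcl13 remained without dexamethasone replicate 1, while Icam1 also lost its call without dexamethasone replicate 3 (adjusted p = 0.0687) and with the replicate block (0.114), and Cxcl10 with the block (0.107) or the squamous covariate (0.0568). Of 19 myeloid markers, Itgax, an integrin of dendritic cells, fell 1.33-fold and 18 did not pass, and Itgax lost its call without each of the 6 arrays in turn (adjusted p up to 0.225), with the replicate block (0.1025) and with the squamous covariate (0.0586). Adjusted over the list alone, 1 myeloid marker was higher and 4 lower (camera adjusted p = 0.174). Of 15 T and NK cell markers 0 passed, with 3 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone (camera adjusted p = 0.149). Of 11 B and plasma cell markers 0 passed, with 2 lower at an unadjusted p under 0.05 (limma, camera adjusted p = 0.372). Of 12 mast cell and eosinophil markers 0 passed, with 2 lower at an unadjusted p under 0.05 and 1 adjusted over the list alone (camera adjusted p = 0.997), and 1 fell without control replicate 1. Their median was 0.0061 and their mean -0.021.

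Genes of the circadian clock moved in opposite directions. Of 17 measured, 2 rose, 7 fell and 8 did not pass, and adjusted over the list alone 4 were higher and 10 lower. The activator gene Arntl, also called Bmal1, rose 1.82-fold (log2 change 0.86, SE 0.075, adjusted p = 0.00240). The clock output genes Dbp and Tef fell 2.79-fold (log2 change -1.48, SE 0.095) and 1.89-fold (log2 change -0.92, SE 0.071). Nr1d2 and Nr1d1, which encode repressors of Arntl, fell 2.73-fold and 2.66-fold. Camera placed the list below other genes (median -0.42, adjusted p = 0.000421; adjusted p = 0.220 with an estimated correlation). The count of 9 called clock genes was 5 without control replicate 3 or dexamethasone replicate 1 and 4 without dexamethasone replicate 2.

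**Figure D2:**
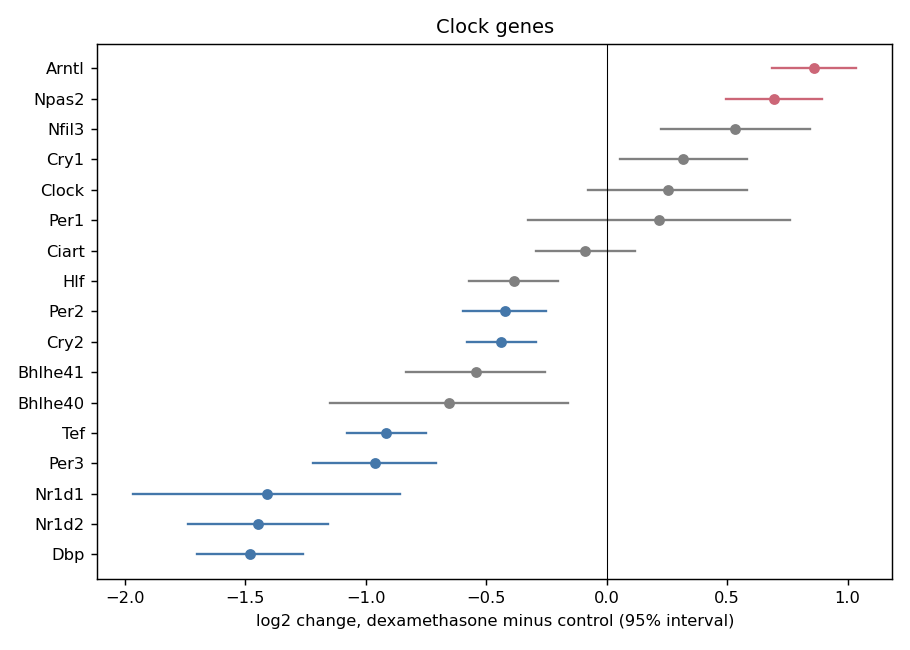
Log2 change of the 17 measured clock genes, dexamethasone minus control, with limma 95% intervals (n = 3 per group). Red points rose and blue points fell past the adjusted threshold, and grey points did not pass. Dbp lies lowest at -1.48 and Arntl highest at 0.86.

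Several metabolic lists differed. Of 16 lipid synthesis genes, 2 fell and 14 did not pass, and 7 were lower adjusted over the list alone. Malic enzyme Me1, a source of NADPH, fell 2.12-fold (log2 change -1.08, SE 0.12, adjusted p = 0.00562) and Cyp51, an enzyme of sterol synthesis, fell 1.69-fold. Fasn, the fatty acid synthase gene, had a log2 change of -0.77 (adjusted p = 0.0778). Camera placed the list below other genes (median -0.42, adjusted p = 3.90e-09; adjusted p = 0.263 with an estimated correlation). The count of 2 was 7 without control replicate 1 and 1 without each of control replicate 2, control replicate 3, dexamethasone replicate 1 and dexamethasone replicate 2. In these last 4 cases it was Cyp51 that lost its call (adjusted p = 0.111, 0.197, 0.1496 and 0.189), as it did with the squamous covariate (0.0547). Of 16 genes of fatty acid oxidation, 2 rose, 0 fell and 14 did not pass, and 6 were higher adjusted over the list alone. Pdk4, a kinase that restrains pyruvate oxidation, rose 2.96-fold (log2 change 1.57, SE 0.23, adjusted p = 0.0186) and the acyl-CoA thioesterase gene Acot2 rose 1.80-fold (adjusted p = 0.0307). Camera gave an adjusted p of 1.80e-05 for that list, and adjusted p = 0.220 with an estimated correlation. The count of 2 was 1 without control replicate 1 and 0 without each of control replicate 2, control replicate 3, dexamethasone replicate 1 and dexamethasone replicate 2. Of 15 genes of xenobiotic metabolism, Ephx1, an epoxide hydrolase, fell 1.49-fold and 14 did not pass. Adjusted over the list alone 7 were lower and 1 higher, the latter being Cyp2b10, named after its values were seen (camera adjusted p = 0.0265; adjusted p = 0.234 with an estimated correlation). The camera adjusted p of the xenobiotic list was 0.0527 without control replicate 2, 0.140 without dexamethasone replicate 3, 0.0592 with the dimmest 40% of genes left out and 0.106 with array weights. Ephx1 lost its call without control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2 and with the replicate block (0.0781), as did Acot2 with the block (0.0907). Of 25 oxidative phosphorylation genes 0 passed (limma, 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.554), though camera called the list higher with the squamous covariate (0.00104) and without control replicate 1 (0.00689). Of 20 unfolded protein response genes 0 passed (1 higher at an unadjusted p under 0.05, camera adjusted p = 0.413), and without control replicate 2 camera called the list lower (0.0114).

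Genes of arginine metabolism were a set of their own, a choice prompted by remembered published work on glucocorticoids and L-arginine in the mouse stomach, which may rest on these same samples. Their counts are therefore not independent evidence. Of 35 measured genes, 1 rose, 1 fell and 33 did not pass, and the same count of 2 passed adjusted over the list alone. Arg2, mitochondrial arginase, rose 3.06-fold (log2 change 1.61, SE 0.14, adjusted p = 0.00238), from 7.55 to 9.16 on the log2 scale. Gatm, the first enzyme of creatine synthesis from arginine, fell 1.40-fold (log2 change -0.48, SE 0.072, adjusted p = 0.0200). Camera did not separate the list from other genes (median 0.05, adjusted p = 0.218). Of 12 nitric oxide and cGMP genes 0 passed (limma, 2 higher and 1 lower at an unadjusted p under 0.05), with Nos1ap at a log2 change of -0.26 and Cav1 at 0.66 (adjusted p = 0.121 and 0.175, camera adjusted p = 0.222 for the list), and without dexamethasone replicate 3 camera called the list higher (0.0217) and 2 genes rose. Arg2 kept its call without each array in turn (adjusted p up to 0.0179), while Gatm lost its call without control replicate 2, control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2 (adjusted p up to 0.124) and with the replicate block (0.0757).

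In the gastric epithelium, the surface mucous cell genes Capn9 and Capn8, which encode gastric calpains, fell 1.70-fold (log2 change -0.76, SE 0.072, adjusted p = 0.00352) and 1.64-fold. The other 9 of 11 surface mucous genes did not pass, and 3 were lower adjusted over the list alone (camera adjusted p = 0.000544; adjusted p = 0.220 with an estimated correlation). The count of 2 was 1 without control replicate 2, control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2. Of 6 neck mucous genes 0 passed (limma, 2 lower at an unadjusted p under 0.05, 1 adjusted over the list alone). Tff2 stood at -0.61 and Muc6 at -0.81 (adjusted p = 0.130 and 0.390). Camera placed the neck list lower (adjusted p = 0.0323; adjusted p = 0.263 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.0517), the dimmest 40% of genes left out (0.0673) or the squamous covariate (0.0510), and without control replicates 2 or 3 (0.0640 and 0.117) or dexamethasone replicate 1 (0.0670), while 2 neck genes passed without dexamethasone replicate 3. Chga, a granule protein of endocrine cells, rose 1.76-fold (log2 change 0.82, SE 0.071, adjusted p = 0.00240). The other 15 endocrine genes did not pass, with 4 higher adjusted over the list alone (camera adjusted p = 0.152, fry adjusted p = 0.0223), and 2 passed without control replicate 1 or dexamethasone replicate 3. Of 19 parietal cell and acid secretion genes 0 passed (limma, 3 higher at an unadjusted p under 0.05, 1 adjusted over the list alone, camera adjusted p = 0.149). Camera called that list higher with the squamous covariate (0.0113) and without control replicate 3 (0.0472) or dexamethasone replicate 1 (0.0288), and without dexamethasone replicate 3, 1 gene rose and 1 fell. Of 6 chief cell genes 0 passed (1 lower at an unadjusted p under 0.05), with a median of 0.064 against a mean of -0.045 (camera adjusted p = 0.595). Of 10 metaplasia genes 0 passed, with 3 higher and 2 lower both at an unadjusted p under 0.05 and adjusted over the list alone (camera adjusted p = 0.416), and 1 rose without dexamethasone replicate 3. Of 24 cell cycle genes 3 fell, the proliferation marker Mki67 1.67-fold, Mcm6 1.47-fold and Kif11 1.43-fold, 21 did not pass, and 15 were lower adjusted over the list alone. Camera placed the cycle list below other genes (median -0.29, adjusted p = 1.79e-13; adjusted p = 0.263 with an estimated correlation), and its 3 calls fell to 0 without control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2, to 1 without control replicate 1 or control replicate 2, and rose to 5 without dexamethasone replicate 3. Kif11 also lost its call with the replicate block (0.0893).

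Among 13 antimicrobial genes, Lcn2 and Lyz1 rose, 11 did not pass, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.0547, fry adjusted p = 0.0369). Camera called this list higher with arrays centred on their median (0.0385) and without control replicates 2 or 3 (0.0184 and 0.0213) or dexamethasone replicates 2 or 3 (0.0139 and 0.0232). The count of 2 was 1 without each array but dexamethasone replicate 3, where 2 rose and 1 fell, as with the replicate block. Of 12 sodium transport genes, Nr3c2 fell and 11 did not pass, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.101; 0.0360 with the replicate block, 0.0331 with the squamous covariate and 0.0197 without dexamethasone replicate 1). Besides Nr3c2, 1 gene rose without control replicate 1, control replicate 2 or dexamethasone replicate 3. The subunits of the epithelial sodium channel, Scnn1a, Scnn1b and Scnn1g, had log2 changes of 0.67, 0.72 and 0.64 (limma adjusted p = 0.0943, 0.0668 and 0.0531).

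In the stroma, 5 of 24 extracellular matrix genes rose, 0 fell and 19 did not pass, and adjusted over the list alone 11 were higher and 1 lower. Lox, which crosslinks collagen and elastin, rose 2.92-fold (log2 change 1.54, SE 0.13, adjusted p = 0.00224), fibronectin Fn1 2.43-fold, elastin Eln 1.81-fold, and the basement membrane collagen gene Col4a2 rose by 0.58 on the log2 scale. Camera gave an adjusted p of 1.34e-09 for the list, and adjusted p = 0.234 with an estimated correlation. Its 5 calls were 2 without control replicate 2, control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2, and Col4a2 also lost its call with the replicate block (0.0595). Of 16 smooth muscle genes, Actg2 rose 1.76-fold and Cnn1 1.66-fold, 14 did not pass, and 8 were higher adjusted over the list alone (median 0.46, or 0.23 with the squamous covariate, camera adjusted p = 6.80e-09; adjusted p = 0.317 with an estimated correlation). Relative to their mean, the dexamethasone arrays lay at 0.39, 0.35 and -0.08 for this list, with controls at -0.31, -0.04 and -0.31, and the highest array of each group was also high for squamous markers. Its 2 calls were 1 without control replicate 1 or control replicate 2, 0 without control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2, and 9 without dexamethasone replicate 3, and Cnn1 also lost its call with quantile normalization (0.0516). Of 9 skeletal muscle genes 0 passed (limma, 5 higher at an unadjusted p under 0.05), with array values of 0.37, 0.79 and -0.28 under dexamethasone (camera adjusted p = 0.000453; adjusted p = 0.393 with an estimated correlation), and 4 passed without dexamethasone replicate 3. Of 12 endothelial genes 0 passed (limma, 5 higher at an unadjusted p under 0.05, 3 adjusted over the list alone), with a camera adjusted p of 0.0231, adjusted p = 0.316 with an estimated correlation. That adjusted p was 0.155 without control replicate 1, 0.0853 without dexamethasone replicate 2 and 0.124 with the squamous covariate, and 1 endothelial gene rose without control replicate 1 or dexamethasone replicate 1.

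In squamous epithelium, Krt6a rose 1.53-fold and the other 15 genes did not pass, with Krt5 at a log2 change of 1.75 (SE 0.61, adjusted p = 0.270). The mean of the squamous list was 0.72 higher under dexamethasone with an SE of 0.64 (camera adjusted p = 0.000421; adjusted p = 0.556 with an estimated correlation), so the difference was about the size of the spread between arrays. The mean was 0.47 without control replicate 1 or dexamethasone replicate 1, 1.14 without control replicate 2 and 1.20 without dexamethasone replicate 3. Krt6a lost its call without control replicate 1, control replicate 3, dexamethasone replicate 1 or dexamethasone replicate 2, and 2 squamous genes passed without dexamethasone replicate 3. Of 3 genes of interstitial cells of Cajal, the chloride channel gene Ano1 fell 1.57-fold (camera adjusted p = 0.139 for the list, fry adjusted p = 0.0267), and Ano1 lost its call without control replicates 1, 2 or 3 (adjusted p = 0.0612, 0.116 and 0.170) or dexamethasone replicates 1 or 2 (0.0516 and 0.157), as well as with the replicate block (0.0546) or quantile normalization (0.0725). Of 17 enteric neuron and glia genes 0 passed (limma, 1 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.333), and without dexamethasone replicate 3 the list was called higher (0.0217) with 1 gene past the threshold. Of 13 pancreatic acinar genes, the lipase gene Cel fell 1.96-fold (adjusted p = 0.00191) and 12 did not pass (camera adjusted p = 0.997), with a median of 0.033 and a mean of -0.11, and 2 fell without dexamethasone replicate 3. In 11 adipocyte genes 0 passed (limma, 2 higher at an unadjusted p under 0.05, camera adjusted p = 0.451), with a median of -0.0066 and a mean of 0.018. In 12 intestinal genes 0 passed (limma, 2 higher and 1 lower at an unadjusted p under 0.05, 1 adjusted over the list alone, camera adjusted p = 0.910), with a median of 0.014 and a mean of -0.0034. Of 3 erythroid genes 0 passed (limma, 1 lower at an unadjusted p under 0.05 and adjusted over the list alone, camera adjusted p = 0.162, fry adjusted p = 0.0275 with a mean of -0.23). Of the 36 lists, camera called 15 with the preset correlation, 7 higher and 8 lower, and 0 with an estimated correlation, where 7 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.220. Fry, which asks only whether a list's genes move one way on balance, called 12, 5 higher and 7 lower. Camera's 15 and fry's 12 were partly different lists. Fry did not call cell cycle (fry adjusted p = 0.0600), lipid synthesis (0.0713), endothelium (0.0816) or smooth muscle (0.111). Nor did it call neck mucous (0.118), skeletal muscle (0.230) or squamous epithelium (0.433). It called the antimicrobial, endocrine, Cajal and erythroid lists, which camera with the preset correlation did not.

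**Figure D3:**
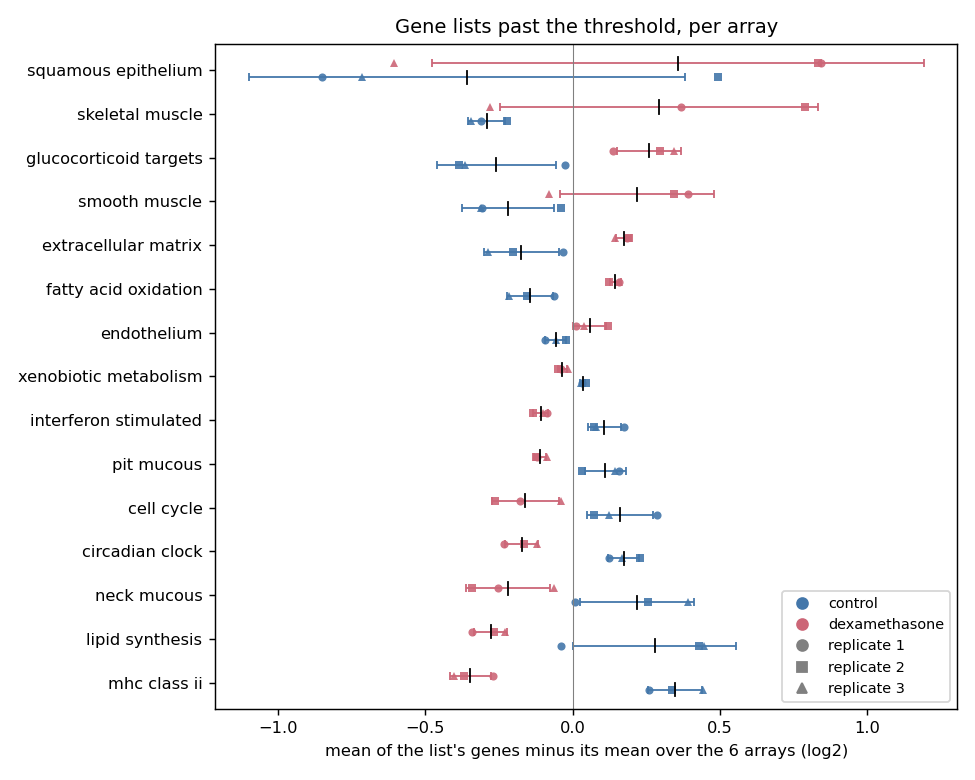
Mean of each called list's genes per array, relative to the mean over the 6 arrays (log2), for the 15 lists past the camera threshold. Points are arrays shaped by replicate, upright marks are group means and bars are SDs (n = 3 per group). For smooth muscle the arrays of dexamethasone lie at 0.39, 0.35 and -0.08, and the squamous list differs within both groups.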

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

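The splits of the arrays were planned, and the covariate on squamous content was chosen after the arrays had been seen to differ in it. Of the probe sets without a gene symbol in the annotation used here, which no comparison above covers, 18 of 1064 passed the threshold when all probe sets were tested with limma, 10 higher and 8 lower, or 1.69% against 1.84% of the named genes. The largest rise among them was 2.14 and the largest fall -1.07 on the log2 scale. Their genes stay unnamed here.

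The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, reached its own counts. The real split gave 367 genes, and the highest other split gave 144. That other split set control replicates 1 and 3 and dexamethasone replicate 3 against the rest, which is the division by squamous content, and it points to a structure of the samples. With that content as a covariate, dexamethasone changed 465 genes, 294 of them among the 367. For the gene lists the real split gave 15, and the others gave 4, 0, 8, 12, 9, 10, 8, 10 and 7. All of these but the split with 144 genes called 0 genes, so list calls also arose where no single gene passed. The other splits still hold unequal numbers of treated arrays, so they are no null free of the treatment. For the arginine genes the real split gave 2 and the highest other 0.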

How the results depend on the processing

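The covariate on squamous content was added after seeing the data, and the other settings were planned. Across settings the 367 genes kept their direction wherever they were tested. Leaving out an array could not reverse it, since the groups of these genes do not overlap. The same holds for array weights. The replicate block, the trend and robust prior and leaving out dim genes keep each log2 change as it was. Only centring, quantile normalization, the squamous covariate or, for 2 symbols, another probe set could have reversed a direction. The median change of all genes was no further from 0 than 0.015 on the log2 scale, from -0.014 to 0.0056. Centring on the median gave 368 genes (348 of the 367), quantile normalization 370 (336), leaving out the dimmest 40% of genes 348 (326), the trend and robust prior 370 (349) and the squamous covariate 465 (294), which raised the arginine count over the list alone to 4. Centring and quantile normalization were weak checks, since RMA normally includes the latter and the array medians already lay between 7.94 and 7.98. Other choices among probe sets moved no call, since only 2 symbols have more than 1. Array weights, which rest on 6 arrays, gave 1776 genes, 773 higher and 1003 lower, 367 of them shared, with 6 arginine genes and 10 over the list alone. Control replicate 3 and dexamethasone replicate 2 had weights of 2.51 and 2.45, against 0.45 to 0.93 for the others, so that fit rested mainly on these arrays. A minimum log2 change of 1 left 48, 26 higher and 22 lower, by construction. With each array left out in turn the genes ranged from 88 to 543, higher ones from 39 to 284, lower ones from 48 to 297, arginine genes from 1 to 3 and over the list alone from 2 to 4, with fewer arrays in each fit. Of the 57 named genes past the threshold, 31 kept it without each array in turn and 43 in every other setting. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, with 7 at an unadjusted p under 0.05. Fry called 12, not all of them among the 15 of the main test. The squamous list under its own covariate is not given, since the covariate removes it by construction. The labels' replicate numbers were tested as a block. Same-numbered arrays' deviations correlated at -0.28, 0.35 and 0.23, and 2 of 6 arrays correlated best with their own number. This gave no clear sign that the numbers pair the samples, but 3 arrays per group cannot exclude it. The block gave 220 genes, 104 higher and 116 lower, 203 of them shared, and 1 arginine gene. Except where the construction shows it, the cause was not tested. Levels near the array background compress changes, and no detection call was used here.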

Other observations

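All tests in this part except the one on NRF2 genes not called singly were chosen after their result was seen. The NRF2 list was drawn up after several of its members had been noted to fall, so no p is given for it. Of these tests, 5 replaced earlier versions that had been run. A bound of 2 SE gave way to a 95% t interval. The tests of epithelium and muscle wall first used a Cajal list of 3 genes that go both ways and would have spoken against both causes (gaps of 0.35 and 0.53). The test against surface mucous cells first used all of their genes (-0.31), most of them near the top of the array's range. Further, a count of clock genes without overlap (9 of 9) was dropped because each called gene meets it, and a count of NRF2 genes kept with the squamous covariate (12 of 17) gave way to a mean. The genes of the next paragraph were chosen after their values were seen.

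Of 32 measured genes known as targets of the antioxidant transcription factor NRF2, 17 fell, 0 rose and 15 did not pass (limma), with a median log2 change of -0.43. Besides Nqo1, Gsta3 and Akr1b8, these included Slc7a11, the cystine transporter (log2 change -0.70, SE 0.066), Ugdh (-0.86, SE 0.090) and Ptgr1 (-1.11, SE 0.11). Hmox1, another target, stood at 0.11 (adjusted p = 0.718). Me1 and Ephx1 are shared with the lipid synthesis and xenobiotic lists. Among genes known from macrophages, Cd163 rose by 1.14 (SE 0.085, adjusted p = 0.00147) and Lyve1 by 1.22 (SE 0.15, adjusted p = 0.0105), while Folr2 stood at 0.41 (adjusted p = 0.0712), Mrc1 at 0.23 (adjusted p = 0.291), Aif1 at -0.32 (adjusted p = 0.105) and Adgre1 at -0.22 (adjusted p = 0.163). Of the gasdermin C genes, Gsdmc4 fell (-0.66, SE 0.12, adjusted p = 0.0385) and Gsdmc stood at 0.13 (adjusted p = 0.906). Scd1, a fatty acid desaturase, had a log2 change of -2.17 (SE 0.56, adjusted p = 0.130).

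The fall of the NRF2 genes may reflect less activity of that factor under dexamethasone, a hypothesis found and examined on the same data. A lower share of surface mucous cells stays open, since 8 of their 11 genes lie in the top percent of levels, where a fall can be compressed. The NRF2 mean differed from that of the other 3 by -0.0053 (SE 0.11, 95% interval from -0.30 to 0.29). Those 3 include Capn9 and Capn8 (log2 changes -0.76 and -0.71), the only called surface mucous genes, so the closeness rests mostly on them. Squamous content as the whole cause goes against the mean shift of -0.53 (SE 0.041) with the squamous covariate, next to -0.53 (SE 0.031) without it, although 5 of the 17 called genes lost their call with it. The 15 members not called singly had a median of -0.17, which decides nothing, since the calls themselves made this subset of a list chosen for its fall. Changes in other cells that express these genes were not tested.

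The clock genes could differ because dexamethasone shifts the clock or because the groups were dissected at different hours. More squamous tissue as the cause goes against 9 of the 9 called clock genes staying past the threshold with the squamous covariate. Of all 367 called genes 294 also stayed, so this is not particular to the clock. An index over the 17 measured clock genes took those in phase with Arntl minus the others. Its control arrays lay from -0.78 to -0.53 and its dexamethasone arrays from 0.59 to 0.67, so no array lay with the other group. The gap of 1.12, with a pooled SD within groups of 0.10, was partly set in advance, since the 9 called genes in it do not overlap. It is therefore no separate test of a single array out of phase. The hour of dissection and the treatment cannot be told apart, since 0 of 126 label fields give a clock time.

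The smooth muscle list may be higher because more muscle wall was dissected in the dexamethasone samples, because epithelium made up less of them, or because its genes were induced. Squamous content as the whole cause goes against the mean shift of 0.25 (SE 0.047, 95% interval from 0.097 to 0.40) with the squamous covariate, but part moves with it, since the shift was 0.44 (SE 0.18) without. A smaller share of epithelium would raise the other cell types alike and stays open, as the pair of 4 such lists farthest apart for its SE, endothelial against myeloid, differed by 0.17 (SE 0.045, interval from -0.051 to 0.38 with Bonferroni correction over 6 pairs). More muscle wall would raise enteric neurons and glia too and also stays open, as smooth muscle exceeded that list by 0.38 (SE 0.15, 95% interval from -0.033 to 0.79). Induction was not tested.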
